A study of Homo sapiens with 9 samples.

How the data were processed

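Gene expression was measured in human CD34-positive progenitors from mobilized peripheral blood after expansion to day 6 and 2 h in erythroid medium with vehicle, BIO or BMP4, with 3 arrays for each of the 3 groups. Per the labels' protocols, RNA was extracted with a column kit for small samples and labelled with a 3′ in vitro transcription kit, and the arrays were Affymetrix Human Genome U133 Plus 2.0. The dose of BMP4 is given per microlitre in the labels, as printed in the report. The solvent of the vehicle is not named.

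The deposited values of the 9 arrays form 1 table of 54675 probe sets. They are MAS5 signals per the submitters' processing notes, on a log10 scale. The log base is not stated and was read from the deposited values, which run from -0.631 to 4.89 with a median of 1.90. As log10 values they give signals of up to 77813 and a median of 79.3, while log2 or natural log values would give maxima of 30 or 133. The steps between the hybridization spike-ins were also set against their nominal amounts. From bioB to bioC the deposited values rose by 0.439 and from bioC to bioD by 0.631, against nominal steps of 0.523 and 0.699 on a log10 scale and of 1.20 and 1.61 on a natural log scale. From bioD to cre, the brightest, they rose by 0.336, further below the nominal 0.602 (log10) or 1.39 (natural log). The sorted values of the 9 columns differ by at most 0.00036, so the arrays had been brought to 1 common distribution before deposit, a quantile normalization that no source used here states. Such a step forces equal distributions on all arrays and would hide any change in the total amount of RNA. No scan dates or detection calls were used here, and no array batches are given in the sources used here.

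All 9 columns were matched to samples by their names. The values were turned back to the linear scale, 12.78 was added, the 20th percentile of all signals, and log2 was taken. A fold change is therefore on the scale of log2 of signal plus 12.78 and understates the change of low genes. Signals in the text are on the linear scale without the added constant, as mean ± SD of 3 arrays. A probe set was kept if its signal was above the 40th percentile of its array, about 48.7, on at least 3 of the 9 arrays. The 62 Affymetrix control probe sets and 70 probe sets of sex-linked genes were left out, the latter because the cells came from people. This left 35696 probe sets, 65.3%.

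Names came from the platform annotation, with symbols updated through the Entrez gene number, which matched 41043 of the 41097 probe sets with 1 gene. A further 1801 probe sets had several genes and 11777 none in that table, and these are unnamed here. The kept probe sets with 1 gene numbered 28143 and stood for 14539 genes. No coordinates are given because no genome build goes with the files.

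Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit on group means over all 9 arrays, contrasts, eBayes with a trend of the variance on the mean signal, two-sided, 6 residual and 9.61 prior degrees of freedom). P-values were adjusted over all kept probe sets by Benjamini-Hochberg and the threshold was 0.05. Simulated data with the real means and spreads and 200 changed probe sets were used to test the fit. For BIO against vehicle, run on 35696 probe sets, it recovered 10.4%, 49.3% and 74.2% of the probe sets changed by 0.5, 1 and 2 on the log2 scale, with 3 false calls. For BMP4 against vehicle it recovered 7.46%, 40.3% and 74.2%, with 4 false calls.

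The report's 22 gene lists, with 460 distinct genes of which 389 were measured, were written from general knowledge before the data were examined, as were the comparisons, the filter, the added constant and the rule for naming genes. Each gene of a list stood for its kept probe set with the highest mean log2 signal. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 22 lists, with camera at an estimated correlation and fry beside it. Fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The genes named are, for each treatment against vehicle, the 10 with the largest rise and the 10 with the largest fall among called probe sets without overlap of the groups. In this ranking each gene stood for its probe set of lowest p. Where fewer than 10 passed, the genes of lowest p were added up to 10. Pathway readouts were given whatever their result, as were up to 4 called members of each list or, if there were none, the 1 or 2 of lowest p (for BMP4 a part of these), and up to 10 genes in each direction for BMP4 against BIO. The symbols of list members adjusted over the list alone and of the 3 lists in the closing section were named after their values were seen.

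RNA and labelling were checked with the log2 ratio of the 3′ to the 5′ control probe set of ACTB and GAPDH and with the mean log2 signal of the spike-in controls, compared by exact two-sided permutation tests. For the shared vehicle arrays, 100 data sets of unchanged groups with the observed spread were simulated. The alternatives tried were no added constant, a constant at the 40th percentile, no filter, a filter at the 60th percentile, a further quantile normalization, other variance models, array weights, only the 6 arrays of a comparison, the replicate number as a block, 1 probe set per gene, the mean over a gene's probe sets, and each array left out in turn. After the data were seen, the 3′ to 5′ ratio and the spike-in level were each added as a covariate, and vehicle replicates 1 and 2, which had the highest 3′ to 5′ ratios, were left out together.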

Results

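The experiment asked which genes respond first when BMP or Wnt signalling is stimulated at the start of human erythroid differentiation. CD34-positive progenitors from mobilized peripheral blood were expanded until day 6 and then held for 2 h in erythroid medium, which contained stem cell factor, erythropoietin, interleukin 3, dexamethasone and estradiol. The medium carried vehicle, BIO at 0.5 µM or recombinant human BMP4 at 25 ng/µl, the unit given with the samples. BIO is 6-bromoindirubin-3′-oxime, an inhibitor of the kinase GSK3 that is used to stabilise β-catenin and so to activate Wnt signalling. BMP4 is a secreted ligand that signals through SMAD1, SMAD5 and SMAD8. RNA from 3 biological replicates of each group was measured on 9 single-colour Affymetrix arrays with 54675 probe sets. Nothing in the sources used here says whether the replicates came from separate donors or cultures, so the p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision. The median standard error of a log2 change was 0.22 over the 35696 probe sets tested, with a 10th to 90th percentile of 0.10 to 0.58.

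The vehicle arrays had the highest group means in the RNA and labelling controls. The log2 ratio of the 3′ to the 5′ probe set of ACTB was 3.26 ± 0.26 (SD, n = 3) with vehicle, 2.84 ± 0.36 with BIO and 2.84 ± 0.11 with BMP4. For GAPDH the same ratio was 1.38 ± 0.17, 0.97 ± 0.20 and 1.02 ± 0.04. In both genes the exact two-sided permutation p was 0.2 for BIO and 0.1 for BMP4, and 0.1 is the smallest p that 3 against 3 arrays can give. The mean log2 signal of the hybridization spike-ins was 13.73 ± 0.08 with vehicle, 13.42 ± 0.06 with BIO and 13.47 ± 0.08 with BMP4, without overlap between vehicle and either treatment (exact permutation p = 0.1 for each). A larger 3′ to 5′ ratio is a common sign of shorter RNA or less complete amplification. These differences ran along with each comparison against vehicle, whereas the comparison of BMP4 with BIO had treated arrays on both sides.

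**Figure D1:**
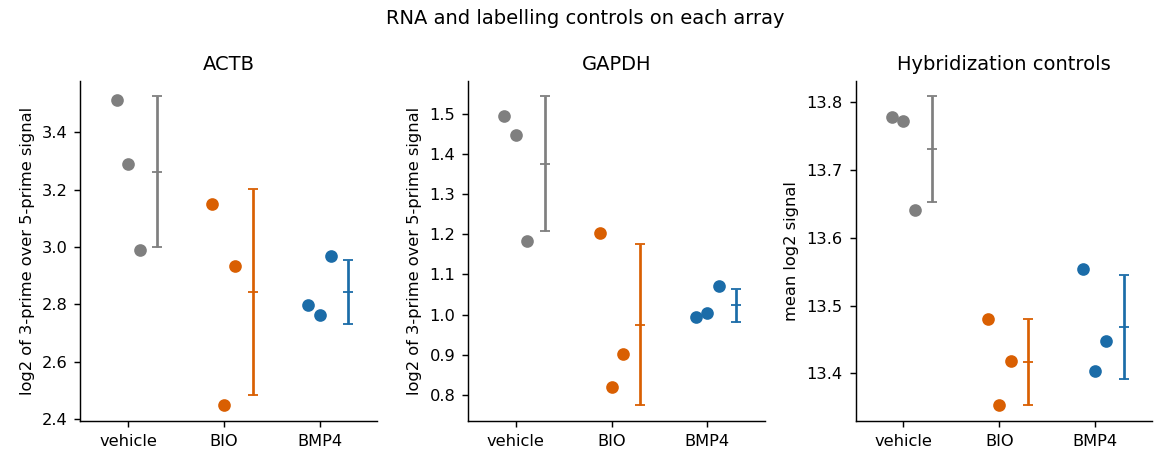
The log2 ratio of 3′ to 5′ signal for ACTB and GAPDH and the mean log2 signal of the hybridization controls (vertical axes) are plotted for the 9 arrays by group. Points are arrays, and the bars give the mean ± SD of 3 arrays. Vehicle had the highest group mean in each panel, 3.26, 1.38 and 13.73.

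The comparison of BIO with vehicle asked which genes respond to GSK3 inhibition within 2 h. The clearest change was a rise of genes controlled by the aryl hydrocarbon receptor, a ligand-activated transcription factor for which indirubins are known ligands. CYP1A1, which encodes a cytochrome P450 and is the classical target of this receptor, had a signal of 43.2 ± 24.5 (SD, n = 3) with vehicle and 1321 ± 194 with BIO. That is a log2 change of 4.69 with a standard error of 0.33 (limma adjusted p = 1.83e-06). CYP1B1, a related cytochrome P450, went from 10140 ± 43.6 to 28400 ± 297, a log2 change of 1.48 with a standard error of 0.055 (adjusted p = 5.72e-10), and its 3 probe sets all rose. AHRR, which encodes the repressor of the receptor, went from 3511 ± 1420 to 9068 ± 577 (log2 change 1.43, adjusted p = 0.000879). TIPARP, an ADP-ribosyltransferase of the same feedback, went from 1556 ± 127 to 3352 ± 135 (log2 change 1.10, adjusted p = 2.56e-05).

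Of the 17 aryl hydrocarbon receptor target genes fixed before the data were examined, 14 were measured, 4 rose, none fell and 10 did not pass the test. Adjusted over the list alone, 7 rose, the further 3 being NFE2L2, NQO1 and PTGS2 with log2 changes of 0.30, 0.46 and 0.64. The list stood higher than the other genes (camera adjusted p = 2.18e-06, median log2 change 0.33, 11 of 14 members positive), but with adjusted p = 0.073 with an estimated correlation the call was lost. The self-contained fry test gave an adjusted p of 0.00044. With the spike-in level as a covariate the call of the list was lost too, the mean log2 change going from 0.76 to 0.41 (adjusted p = 0.0675).

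On the scale with the added constant, the largest rises with BIO outside this list were in SECTM1 and GPR35. SECTM1, which encodes a secreted and transmembrane protein, went from 96.6 ± 16.7 to 414 ± 102 (log2 change 1.94). GPR35, a G protein-coupled receptor, went from 71.8 ± 35.9 to 269 ± 47.3 (1.82). FUCA1, a lysosomal fucosidase, went from 1023 ± 90.1 to 3065 ± 151 with a log2 change of 1.57 and an adjusted p of 7.09e-07. C11orf21, CCL2, MEIOC and RASAL1 rose from low signals with vehicle, 26.8, 48.4, 42.2 and 59.1, by log2 changes of 1.80, 1.70, 1.52 and 1.45. C11orf21 and MEIOC each had a further probe set with the opposite sign. With 1 array left out these 4 calls were kept in 1, 5, 2 and 6 of 9 fits, with adjusted p up to 0.153, 0.14, 0.245 and 0.115, and that of GPR35 in 8 (0.073 without BIO replicate 2). With BMP4 the log2 changes of C11orf21, CCL2 and RASAL1 were 1.45, 1.28 and 1.06, not passing, and their differences between the treatments had adjusted p of 0.882, 0.815 and 0.786. The differences of GPR35 and MEIOC did not pass either (limma adjusted p = 0.181 and 0.245). The largest falls of named genes were those of PRKDC, the catalytic subunit of a DNA repair kinase (log2 change -1.29), KLHL24 (-1.27), UBALD2 (-1.19), RASEF (-1.15) and CCND1, which encodes cyclin D1 (-1.04). MYCN, a MYC family transcription factor, went from 663 ± 64.3 to 329 ± 51.3 (log2 change -0.99, adjusted p = 0.00392). ANKRD36, NUP210, ASPM and ARMC8 fell by 0.97, 0.97, 0.89 and 0.89 on the log2 scale. Between BMP4 and BIO these 4 had log2 differences of 0.37, 0.52, 0.008 and 0.76, none passing (limma adjusted p = 0.487, 0.392, 0.997 and 0.0829). The difference of PRKDC there was 0.99 and did not pass (limma adjusted p = 0.12). PRKDC, MYCN, NUP210, ASPM and ARMC8 each had at least 1 other probe set of the opposite sign. For KLHL24 all 5 probe sets had negative changes, and 3 of them passed. The calls of PRKDC, NUP210, ASPM and ARMC8 were kept in 6, 6, 7 and 6 of the 9 fits, each being lost without BIO replicate 2 and without vehicle replicate 2.

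In all, 260 probe sets differed between BIO and vehicle by the limma test, 136 higher and 124 lower with BIO, which stood for 181 named genes (106 higher, 75 lower). A further 50 called probe sets had no single gene name, and 43 of these were lower. All 260 had no overlap between the 3 treated and the 3 vehicle arrays, against 15% of all tested probe sets and 10% expected by chance, and 53 changed at least 2-fold. At an unadjusted p under 0.05 there were 4422 probe sets, where 1785 would be expected by chance. The count depended on the variance model and on the arrays. It was 10 without the intensity trend in the variance, 83 with only the 6 arrays compared, 60 with the 3′ to 5′ ratio as a covariate and 2, both for CYP1B1, with the spike-in level as a covariate, where CYP1A1, FUCA1 and TIPARP had log2 changes of 3.88, 1.31 and 1.30 with standard errors of 0.75, 0.23 and 0.23, against 0.33, 0.10 and 0.10 without it, and adjusted p of 0.353, 0.195 and 0.195. It was 94, 74 and 720 without vehicle replicate 1, 2 or 3, 68 without BIO replicate 2, 165 without BMP4 replicate 2, and 35 without vehicle replicates 1 and 2. Of the 260 called probe sets, 55 kept the call whichever array was left out, in 43 named genes, among them CYP1A1, CYP1B1, AHRR, TIPARP, FUCA1, SECTM1, KIT, EGR1, CCND1, MYCN, KLHL24, UBALD2, RASEF, ANKRD36 and DUSP6. With BMP4, 231 of the 260 changed in the same direction against the same vehicle arrays. In the direct comparison of the treatments 75 of the 260 differed, while ANKRD36 and DUSP6 did not pass (limma adjusted p = 0.487 and 0.465).

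**Figure D2:**
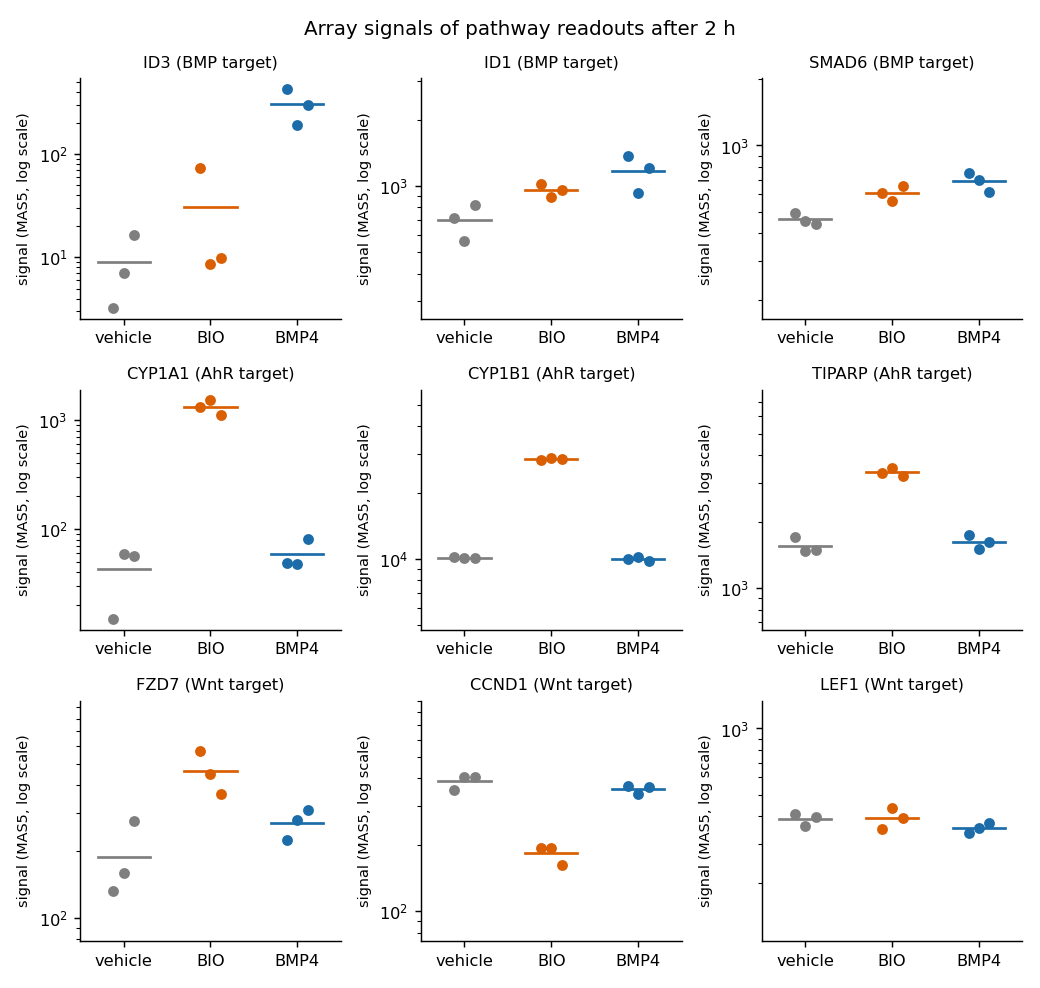
Signals of 9 pathway readout genes on each array (vertical log axes) are plotted by group. Points are the 3 arrays and lines their means, with 3 BMP targets in the upper row, 3 aryl hydrocarbon receptor (AhR) targets in the middle row and 3 Wnt targets in the lower row. CYP1A1 had a mean of 1321 with BIO against 43.2 with vehicle, and ID3 a mean of 304.9 with BMP4 against 8.98.

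Genes that β-catenin is known to activate did not move together with BIO. Of the 30 Wnt-β-catenin target genes listed, 19 were measured, 1 rose, 1 fell and 17 did not pass. FZD7, a Wnt receptor, rose from 190 ± 76.1 to 462 ± 103 (log2 change 1.27, adjusted p = 0.0245) on both of its probe sets, a call that was lost without vehicle replicate 1 or 2 or without BIO replicate 1 or 2 (adjusted p from 0.00346 to 0.126 over the 9 arrays left out). Between BMP4 and BIO neither probe set of FZD7 passed (log2 differences -0.74 and -1.37, limma adjusted p = 0.374 and 0.0694). CCND1, named above, fell from 390 ± 30.2 to 183 ± 18.1 (adjusted p = 0.00627). LEF1, a transcription factor of the pathway and itself a target, was at 389 ± 25.3 with vehicle and 393 ± 43.5 with BIO (log2 change 0.01, standard error 0.15). The log2 changes of the feedback genes NKD1 and ZNRF3 were 0.03 and -0.17, and that of MYC was -0.21 (adjusted p = 0.415). AXIN2, the most widely used readout, had 4 probe sets, none of which passed the signal filter, with signals of 3.26 to 55.6. TCF7 had no probe set named for it alone. As a list the targets tended lower (camera adjusted p = 0.0548, 0.406 with an estimated correlation, median log2 change -0.16), short of the threshold. The list was called lower in 7 of 21 alternatives, namely without the added constant (adjusted p = 0.0496), without vehicle replicate 1 (0.00743), BIO replicate 2 (0.0413) or BIO replicate 3 (0.0469), without vehicle replicates 1 and 2 (0.0119), and with the 3′ to 5′ ratio (0.00122) or the spike-in level (0.000833) as a covariate. None of the 26 measured Wnt pathway components passed (camera adjusted p = 0.676), and APC and TLE3, the members of lowest p, had log2 changes of 0.32 and -0.24.

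The list of integrated stress and unfolded protein genes also stood higher with BIO. All 18 members were measured, 2 rose and none fell, and the median log2 change was 0.13 with 15 members positive (camera adjusted p = 0.00575, fry adjusted p = 0.0296). The call was lost with an estimated correlation (adjusted p = 0.268), without vehicle replicate 3 or BIO replicate 1, and with the spike-in level as a covariate, where the mean log2 change stayed at 0.23 (adjusted p = 0.119). The members that rose were VLDLR, a lipoprotein receptor, by a log2 change of 0.89 (adjusted p = 0.0488), and SLC7A11, the cystine transporter, by 0.69 (adjusted p = 0.0384). Both had adjusted p above 0.05 in most of the fits without 1 array, up to 0.175 and 0.174. The other probe set of SLC7A11 rose by 0.89 (adjusted p = 0.0102), a call kept in 6 of the 9 fits. Between BMP4 and BIO neither VLDLR (limma adjusted p = 0.5) nor SLC7A11 (0.111 and 0.157) passed. HSPA5, the chaperone BiP, passed only when adjusted over the list alone (log2 change 0.31). Hybridization controls, as given above, were lower on the BIO than on the vehicle arrays.

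Some blood cell genes changed with BIO, and no blood cell list passed the camera test. In the stem and progenitor list of 24 genes, 21 were measured, 1 rose and 2 fell (camera adjusted p = 0.273). KIT, the receptor of stem cell factor, rose from 5754 ± 254 to 10530 ± 126 (log2 change 0.87, adjusted p = 2.05e-05). The transcription factor genes MEIS1 and ERG fell by 0.58 and 0.58 on the log2 scale, MEIS1 with adjusted p = 0.0765 without BIO replicate 2, and ERG with a call in only 1 of the 9 fits that each left out an array. CD34 was at 509 ± 115 with vehicle and 449 ± 98.1 with BIO and did not pass, nor did GATA2 (log2 change -0.14), while RUNX1 had no probe set named for it alone. None of 24 measured erythroid genes passed (camera adjusted p = 0.431). GATA1 and KLF1, the main erythroid transcription factors, had log2 changes of -0.29 and -0.29 with adjusted p of 0.33 and 0.305, ZFPM1 one of -0.38 and RHD one of 0.89. Of 21 neutrophil and monocyte genes, CEBPA, a myeloid transcription factor, rose by 0.40, and of 16 megakaryocyte genes CD9 rose by 0.68, the 2 lists having camera adjusted p of 0.0548 (adjusted p = 0.268 with an estimated correlation) and 0.636. The neutrophil and monocyte list, with 16 of 21 members positive, had a fry adjusted p of 0.0203 and was called higher in 6 of 21 alternatives. The other probe set of CD9 had a log2 change of -1.18, and 1 of the other probe sets of ERG one of 0.04, neither passing. The CEBPA call was kept in 2 and the CD9 call in 1 of the 9 fits without an array. Between BMP4 and BIO, KIT and CEBPA differed (limma adjusted p = 6.46e-05 and 0.0278). MEIS1, ERG and CD9 did not pass there (limma adjusted p = 0.0616, 0.0976 and 0.738). No mast cell, basophil and eosinophil gene among 14 and no lymphoid gene among 14 passed (camera adjusted p = 0.815 and 0.772), FCER1A, CPA3, IL7R and NKG7 having the lowest p with log2 changes of 0.37, 0.20, 0.81 and 0.36.

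Single members of the remaining lists responded to BIO. EGR1, an immediate early transcription factor, rose from 2096 ± 144 to 3841 ± 360 (log2 change 0.87, adjusted p = 0.000235), the 1 of 21 measured immediate early genes to pass. DUSP6, a phosphatase of the ERK pathway in the cytokine feedback list, fell from 2950 ± 295 to 1629 ± 280 (log2 change -0.86, adjusted p = 0.00289), the 1 of 19 there. Other probe sets of DUSP6 had log2 changes of -0.37 and -0.11 and did not pass (adjusted p = 0.128 and 0.861). A dimmer probe set of CCND2 in the cytokine feedback list was also called (-0.76, adjusted p = 0.0486, kept in 3 of 9 fits without an array). Of 17 glucocorticoid targets, DDIT4 and TSC22D3 rose by 0.76 and 0.56, TSC22D3 with another probe set at -1.03 that did not pass. CCL2 was the 1 of 17 inflammatory genes, RSAD2 (log2 change 0.60) the 1 of 14 interferon-stimulated genes and INSIG1 (0.37) the 1 of 12 cholesterol synthesis genes to rise, and TP53INP1 (-0.63) the 1 of 15 p53 targets to fall. Of the 9 fits without an array, the calls of DDIT4, TSC22D3, CCL2, RSAD2, INSIG1 and TP53INP1 were kept in 6, 3, 5, 7, 5 and 4, with adjusted p up to 0.0979, 0.146, 0.14, 0.0922, 0.117 and 0.148, and all 6 were lost without BIO replicate 2. Another probe set of INSIG1 rose by 0.79 (adjusted p = 0.00789), kept in 8 fits, and another of RSAD2 by 0.71 (adjusted p = 0.0412), kept in 0. Between BMP4 and BIO, EGR1, DDIT4 and TSC22D3 differed (limma adjusted p = 0.000365, 0.0144 and 0.00312). RSAD2, INSIG1 and TP53INP1 did not pass there on the probe sets named first (limma adjusted p = 0.0878, 0.446 and 0.0767). No cell cycle gene among 26, heat shock gene among 11, hypoxia and glycolysis gene among 17, BMP pathway component among 16 or BMP-SMAD target among 21 passed on its brightest probe set. A dimmer probe set of ENO1, in the hypoxia and glycolysis list, was called (log2 change 0.84, adjusted p = 0.0281, kept in 5 of 9 fits), while its brightest had -0.01. Their members of lowest p were CCNA2 and CCNE2 (log2 changes -0.30 and -0.32), HSPD1 and BAG3 (0.16 and 0.31), SLC2A1 and P4HA1 (0.63 and 0.25), SKI and BMPR2 (-0.39 and 0.48) and HES1 and FST (-0.64 and 0.98). The camera adjusted p of these 12 lists lay between 0.111, for the inflammatory genes, which were called higher in 2 of 21 alternatives, and 0.968, for the BMP pathway components. The BMP-SMAD targets had an adjusted p of 0.16 and a median log2 change of 0.27, with ID1 at 0.46 and SMAD6 at 0.38, neither passing.

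**Figure D3:**
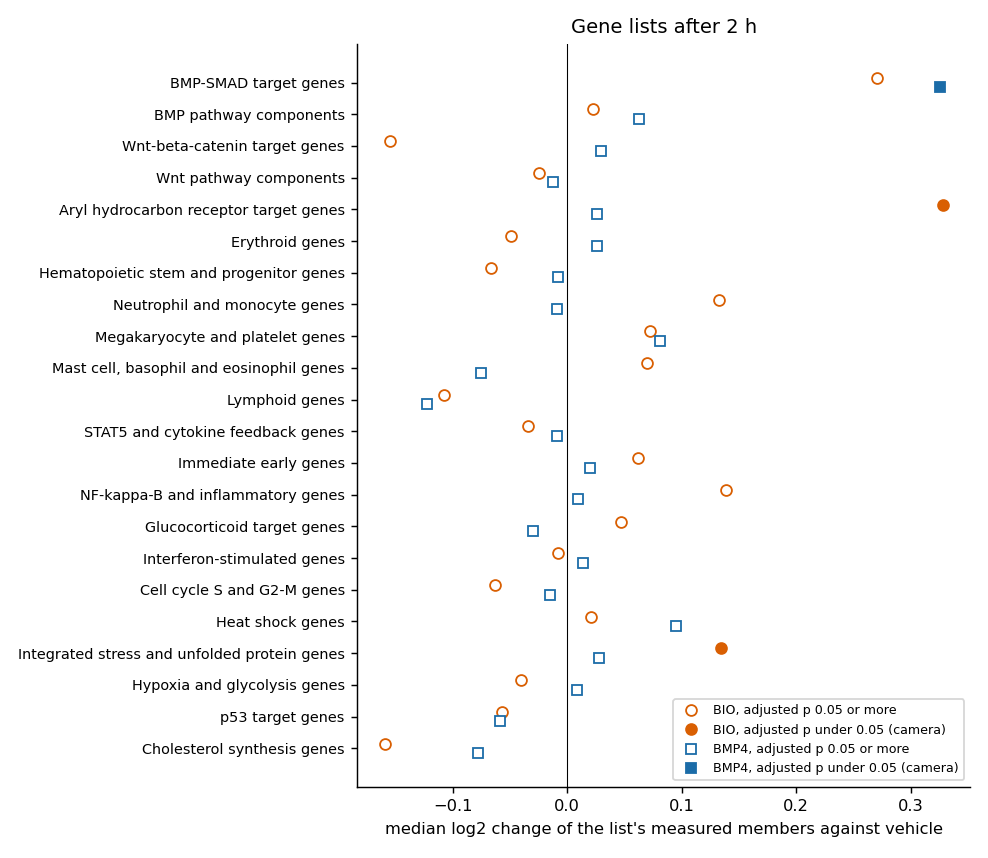
The median log2 change against vehicle of the measured members of each of 22 gene lists (horizontal axis) is plotted for BIO (circles) and BMP4 (squares). Filled symbols have a camera adjusted p under 0.05 at the preset correlation, and these were the aryl hydrocarbon receptor targets (0.33) and the stress genes (0.13) with BIO and the BMP-SMAD targets (0.33) with BMP4. With an estimated correlation all 3 calls were lost (camera adjusted p = 0.073, 0.268 and 0.124).

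The comparison of BMP4 with vehicle asked which genes respond to BMP signalling within 2 h. ID3, which encodes an inhibitor of helix-loop-helix transcription factors and is a direct SMAD target, rose from 8.98 ± 6.89 (SD, n = 3) to 304.9 ± 116, a log2 change of 3.85 with a standard error of 0.56 (limma adjusted p = 0.0497). The vehicle level lay below the filter, so that this change is understated by the added constant. The ID3 call was lost in 13 of 23 alternatives, among them those without the added constant (adjusted p = 0.169), without a filter (0.124), with the filter at the 60th percentile (0.0901), without the intensity trend (0.309) and with a replicate block (0.057). It was also lost without vehicle replicate 1 or 2 or any BMP4 replicate, with adjusted p up to 0.346, while the log2 change stayed between 2.57 and 5.32. The other immediate BMP readouts had positive changes that did not pass over all probe sets. ID1 was at 702 ± 130 with vehicle and 1164 ± 220 with BMP4 (log2 change 0.72, adjusted p = 0.282), and the inhibitory SMAD6 at 464 ± 29.4 and 690 ± 70.2 (0.56, adjusted p = 0.299), each without overlap between the groups. SMAD7 had a log2 change of 0.55, and ID2 changes of 0.20 on its brighter and 0.85 on its other probe set (adjusted p = 0.55 and 0.31). SMAD6 had another probe set at -0.22. The gene BMP4 itself had 1 probe set, below the filter at 4.83 to 10.1.

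Of the 26 BMP-SMAD target genes listed, 21 were measured, 1 rose, none fell and 20 did not pass. Adjusted over the list alone, 5 rose, namely ID3, ID1, SMAD6, SKIL and NOG, the last a secreted BMP antagonist. The list stood higher than other genes (camera adjusted p = 3.51e-05, 19 of 21 members positive, median log2 change 0.33, fry adjusted p = 0.0187). With BIO, against the same vehicle arrays, 18 of the 21 members were positive too, with a median of 0.27 (camera adjusted p = 0.16). Against BIO rather than vehicle, BMP4 had 15 members positive, with a median of 0.17 (camera adjusted p = 0.0123). The call against vehicle was lost with an estimated correlation (camera adjusted p = 0.124). The other 21 lists had camera adjusted p between 0.716 and 0.976, and no member of them passed over all probe sets. Their members of lowest p included ITGB3 (log2 change 0.61), CCL2 (1.28), CDK1 (0.64), XBP1 (0.32), SQLE (-0.36) and DUSP6 (-0.54), with adjusted p of 0.292 to 0.422. Aryl hydrocarbon receptor targets were among them, CYP1A1 being at 59.2 ± 18.9 with BMP4 (log2 change 0.45), CYP1B1 at 10970 ± 137 on its brightest probe set (0.01), AHRR at 4650 ± 507 (0.47) and TIPARP at 1623 ± 119 (0.06). Wnt readouts did not pass either, LEF1, NKD1, ZNRF3 and MYC having log2 changes of -0.13, 0.12, 0.10 and 0.25. The log2 changes of GATA1, KLF1, GATA2 and CD34 were -0.32, -0.24, -0.24 and -0.38, with adjusted p of 0.495 to 0.593.

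Across all probe sets BMP4 changed 3, 1 higher and 2 lower. Besides ID3 these were MALAT1, a nuclear long noncoding RNA, which went from 8342 ± 755 to 5362 ± 118 on 1 of 12 probe sets (log2 change -0.63, adjusted p = 0.0168), and DLGAP4, which went from 927 ± 154 to 414 ± 68.8 on 1 of 5 (log2 change -1.14, adjusted p = 0.0497). The same probe sets of MALAT1 and DLGAP4 fell with BIO too, with log2 changes of -0.80 and -0.81 (limma adjusted p = 7.16e-05 and 0.0288). Between the treatments neither passed (log2 differences 0.17 and -0.33, limma adjusted p = 0.601 and 0.64). These 2 falls therefore cannot be told apart from a difference of the shared vehicle arrays. At an unadjusted p under 0.05 there were 3075 probe sets, with 1785 expected by chance. Next in order of p and not passing were WDR77, DHX9, ASPM, TBL1XR1, DRAP1, DHX36 and MSRB3, all with negative log2 changes, between -1.09 for WDR77 and -0.57 for DHX36, and adjusted p of 0.0718 to 0.132. DHX9, ASPM, TBL1XR1, MSRB3 and MALAT1 each had at least 1 other probe set of the opposite sign. None of the 3 calls held whichever array was left out. The number was 0 without any 1 of the BMP4 replicates, 1 without vehicle replicate 1, 9 without vehicle replicate 3 and 23 without BIO replicate 1. It was 13 with only the 6 arrays compared, among which were all 3 of these calls, and 1 without the intensity trend, which was none of the 3.

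The direct comparison of the treatments does not use the vehicle arrays for its fold changes. Genes of the aryl hydrocarbon receptor list were lower with BMP4 than with BIO, by log2 differences of -4.23 for CYP1A1, -1.51 for CYP1B1, -1.04 for TIPARP and -0.97 for AHRR (limma adjusted p = 8.01e-06, 4.57e-10, 6.46e-05 and 0.028). FUCA1 (-1.34), SECTM1 (-1.92), the chemokine gene CXCL8 (-1.79), GNG12 (-2.03), SIPA1L2 (-1.42), IGFBP4 (-1.34), EPB41L3 (-1.28) and KIF5C (-1.24) were also lower with BMP4. The GNG12 signal with BMP4 was 17.02 ± 9, at which the size of the difference depends on the added constant. ID3 was higher with BMP4, at 304.9 ± 116 against 30.5 ± 36.9 (log2 difference 3.13, adjusted p = 0.0224). Its BIO signals were 73.1, 8.54 and 9.87, so low that the added constant understates this difference. KLHL24 (1.44), MYCN (0.94), CCND1 (0.93), RASEF (0.78), UBALD2 (0.78), NR1D2 (0.75), RNF44 (0.64), CEBPD (0.60) and MNT (0.57) were higher too. With 1 array left out the AHRR difference was kept in 3 of 9 fits, being lost without any of the BIO or BMP4 replicates (adjusted p up to 0.187). Those of GNG12 and MNT were kept in 1, those of NR1D2, RASEF and UBALD2 in 3, those of SIPA1L2, IGFBP4, CCND1, RNF44 and ID3 in 4, those of CXCL8, MYCN and CEBPD in 5 and those of EPB41L3 and KIF5C in 6. ID1 and SMAD6 differed by 0.26 and 0.17 and did not pass, nor did MYC at 0.46 (adjusted p = 0.0805).

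In all, 102 probe sets differed between BMP4 and BIO, 24 higher and 78 lower with BMP4, in 77 named genes. Of the 260 probe sets that BIO changed against vehicle, 75 also differed from BMP4, 59 of them higher with BIO. A further 27 of the 102 were not called for BIO against vehicle. Among the 22 lists, aryl hydrocarbon receptor targets were lower with BMP4 (camera adjusted p = 5.06e-07, 0.0577 with an estimated correlation), as were stress genes (0.0123, 0.274 with an estimated correlation) and neutrophil and monocyte genes (0.023, 0.221 with an estimated correlation). BMP-SMAD targets were higher (camera adjusted p = 0.0123, 0.242 with an estimated correlation). The number of probe sets was 40 without BIO replicate 2, 38, 34 and 44 without BMP4 replicate 1, 2 or 3, and 7 without the intensity trend. Of the 102 probe sets, 28 kept the call whichever array was left out, in 23 named genes, among them CYP1A1, CYP1B1 (3 probe sets), FUCA1, KLHL24, SECTM1, TIPARP, KIT and EGR1. The ID3 difference did not.

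Over the 35696 probe sets, the log2 changes with BIO and with BMP4 had a Pearson correlation of 0.553. Both share the 3 vehicle arrays, and 100 simulated data sets with unchanged groups gave 0.50 on average, with a range of 0.477 to 0.518. The covariance was 0.0827 against 0.0618 (0.0574 to 0.0652) in the simulations, a difference of 0.0209. The 2 changes had the same sign for 70.4% of probe sets, against 66.7% in the simulations. The simulations gave all arrays the same spread for a probe set and drew the probe sets independently. Within groups the vehicle arrays correlated at 0.957 to 0.961, the BIO arrays at 0.961 to 0.966 and the BMP4 arrays at 0.969 to 0.970. A larger spread of the shared vehicle arrays would by itself raise the correlation. The excess over the simulations is therefore not evidence of a shared effect. At the level of calls, no probe set was called higher with both treatments, where 0.0038 would be expected of independent lists, and 2, those of MALAT1 and DLGAP4, were called lower with both, where 0.0069 would be expected. These expectations leave out that the vehicle arrays are shared, so they are not what unchanged groups would give, and the overlap of calls is not evidence of a shared effect. The 3 vehicle arrays are too few to split into 2 parts of at least 2. Probe sets are not independent replicates, and no p is given.

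**Figure D4:**
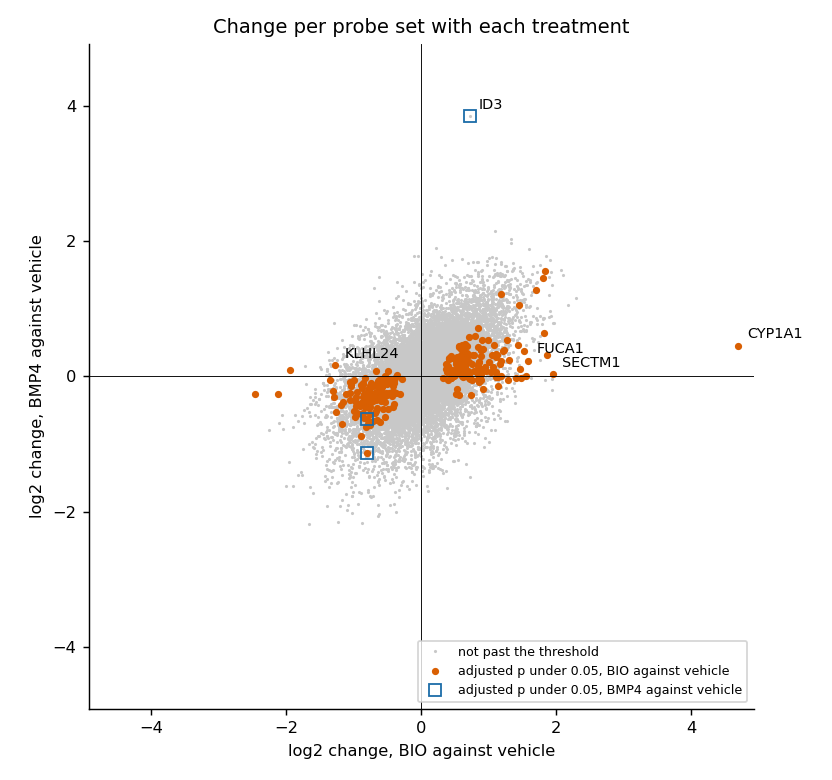
The log2 change of each of 35696 probe sets with BIO (horizontal axis) and with BMP4 (vertical axis) against the shared vehicle arrays is plotted as a point. Filled circles mark the 260 probe sets called with BIO and open squares the 3 called with BMP4. CYP1A1 lies far out along the BIO axis at 4.69 and ID3 along the BMP4 axis at 3.85.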

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

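The 2 covariates and the fit without vehicle replicates 1 and 2 were chosen after the results were seen, and the other alternatives before. The numbers of probe sets changed by BIO, changed by BMP4 and different between them were 260, 3 and 102, and the lists shifted 2 and 1. Without the added constant BMP4 changed 1, not ID3, and BIO shifted 4 lists, the Wnt targets lower. Without a filter BIO changed 153 and BMP4 1, and with the filter at the 60th percentile BMP4 changed 1 and BIO shifted 4 lists. Without the intensity trend the counts were 10, 1 and 7. With array weights BMP4 changed 8 and 187 differed between the treatments. With only the 6 arrays compared BIO changed 83 and BMP4 13, and with 1 probe set per gene BIO changed 165, fewer being tested. With an estimated correlation 0 lists were shifted by BIO and 0 by BMP4. With the 3′ to 5′ ratio as a covariate the counts were 60, 11 and 171. With the spike-in level as a covariate BIO changed 2 and BMP4 0, BIO shifted 1 list and BMP4 2, and the Wnt targets, not called before, had a mean log2 change with BMP4 of -0.199 (adjusted p = 0.0442), the opposite sign. Without vehicle replicates 1 and 2, where the lone vehicle array is assumed to vary like the others, BIO changed 35 and BMP4 0, and BIO shifted 4 lists. Other than fewer probe sets or arrays, the cause was not tested. Further quantile normalization changed nothing, since the arrays already shared 1 distribution.

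Replicate numbers showed no clear pairing of the arrays. Deviations from the group means correlated at -0.0266 to 0.0592 over the 9 pairs between groups with the same number. Over the pairs between groups with other numbers they correlated at -0.0552 to 0.0461. For 0 arrays did the best matches in both other groups have the array's own number. With the replicate number as a block BIO changed 276, BMP4 1 and 84 differed. Leaving out 1 array gave 68 to 720 probe sets with BIO, 0 to 23 with BMP4 and 34 to 119 between them, 1 to 5 lists with BIO and 1 with BMP4, and a correlation of 0.474 to 0.682. The difference in the log2 3′ to 5′ ratio from vehicle was then -0.571 to -0.22 for ACTB and -0.514 to -0.323 for GAPDH with BIO, and -0.556 to -0.295 and -0.448 to -0.293 with BMP4. Over the middle probe set in place of the 5′ one it was -0.0986 (ACTB) and -0.174 (GAPDH) with BIO, and -0.059 and -0.0966 with BMP4. Of the values of called named genes over all alternatives, 1016 stayed past the threshold, 418 did not and 0 changed sign. Signal near background limits low genes such as ID3 with vehicle, where the fold depends on the added constant.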

Other observations

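The tests of other splits, of 3 arrays against 6, of spike-ins and further probe sets for the aryl hydrocarbon receptor genes and of the rest of that list were chosen only after the result was seen, as were the 3 gene lists described first. Camera p-values of these 3 lists, at either correlation, were adjusted over the 3 alone in each comparison. That adjustment is milder than the one for the lists fixed beforehand, so the adjusted values cannot be compared between them.

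Genes for protein entry into the endoplasmic reticulum and folding there tended higher with BIO. Of 36 genes listed 34 were measured, 29 had a positive change, and the median log2 change was 0.16 (camera adjusted p = 0.00011, adjusted p = 0.276 with an estimated correlation). With BMP4 26 were positive, with a median of 0.10 (camera adjusted p = 0.00243, adjusted p = 0.466 with an estimated correlation), but the vehicle arrays are the same, so this is no second observation. With BIO 5 of them had a called probe set. For 2 this was the brightest one, namely PDIA3, a disulphide isomerase, with a log2 change of 0.41 (adjusted p = 0.0213), and EMC3, of a membrane insertion complex, with 0.53 (adjusted p = 0.0343), calls kept in 6 and 4 of the 9 fits without an array. The brightest probe sets of SPCS2, MYDGF and TMED4 had log2 changes of 0.07, 0.25 and 0.15 (adjusted p = 0.715, 0.217 and 0.692). With BMP4 none of the genes had a called probe set. The list was drawn up from these data, so its test is not independent evidence.

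HLA genes had a median log2 change of 0.08 with BIO over 17 measured members, 13 positive (camera adjusted p = 0.0214, adjusted p = 0.384 with an estimated correlation), and 3 had a called probe set, among them HLA-DRA, with a log2 change of 0.61 (adjusted p = 0.0332) and a call kept in 2 of the 9 fits without an array. The brightest probe sets of the other 2, HLA-B and HLA-G, had 0.03 and 0.14 (adjusted p = 0.902 and 0.443). Nuclear-retained RNAs and splicing regulators had a median of -0.06 over 28 (camera adjusted p = 0.0303, adjusted p = 0.405 with an estimated correlation), with a called lower probe set in 4. MALAT1 and LUC7L3 fell by 0.51 and 0.31 on the log2 scale, the LUC7L3 call (adjusted p = 0.0442) being kept in 1 of the 9 fits, while the brightest probe set of ARGLU1, another of the 4, had 0.16. With BMP4 the adjusted p of these 2 lists were 0.113 and 0.589. Both lists were chosen after the result was seen, so their tests are not independent evidence either.

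At an unadjusted p under 0.01 in both comparisons, 242 probe sets moved the same way with BIO and BMP4, 131 higher and 111 lower, and 1 moved in opposite ways. Set against the other 6 arrays, the vehicle arrays gave 1101 probe sets at this p. Of the 84 choices of 3 arrays, 4 gave as many, among them the vehicle arrays themselves and the BIO arrays (1230). The choices that mixed groups were vehicle replicates 1 and 2 with BIO replicate 1 (2137, the highest) or with BMP4 replicate 1 (1115). Those that gave 2137 were the 3 arrays with the highest mean 3′ to 5′ ratio of ACTB and GAPDH. The mixed choices point to a structure of the samples other than the groups. The change predicted from the slope within groups made up a median of 23% of the shared change for the 3′ to 5′ ratio (18.1% to 32.8% without 1 array) and 48.9% for the spike-in level (32.6% to 71.2%), against 37.4% and 70.3% in other probe sets. RNA quality or labelling may thus account for a part of it, and a response common to both treatments cannot be told apart from them, because vehicle had the highest mean of the 3 groups in each of these controls.

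The rise of the 4 aryl hydrocarbon receptor genes with BIO was set against the same explanations. As a median over their called probe sets, the slope within groups predicted 6.87% of it for the 3′ to 5′ ratio (3.72% to 8.32% without 1 array). For the spike-in level the median was 12.7% (1.87% to 18.8%). These probe sets were called for a large change against a small spread within groups, and the slope comes from that same spread. A low share is thus favoured by the choice of probe sets, and the medians do not exclude either explanation. CYP1B1 had more than 1 of these probe sets and so counts most in the medians. No share was worked out for each gene. With the spike-in level as a covariate the log2 change of CYP1A1 went from 4.69 to 3.88 and that of TIPARP from 1.10 to 1.30. A larger part for a single gene such as AHRR is not excluded. Cross-hybridization of a single probe set is argued against for CYP1B1 alone, where 2 of 2 probe sets besides the one of lowest p were past the threshold. It stays open for CYP1A1, AHRR and TIPARP, which have 0 further probe sets above the filter. A candidate explanation is activation of the receptor by BIO, itself an indirubin; the other 10 measured members had a median log2 change of 0.23, 7 positive, with camera p = 0.0389 but 0.11 with an estimated correlation. That hypothesis therefore stays open for these 4 genes, where no test of it was made, as for the others, and an effect through GSK3 was not tested.

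β-catenin targets were not higher as a list with BIO. On the scale with the added constant, 13 of the 19 measured members had a 95% upper limit under 1.5-fold, among them LEF1, MYC and ZNRF3. This argues against too low a signal to show a rise for these 3, whose vehicle signals were 389, 12820 and 203. For dim members it cannot decide, since the added constant understates their changes. Members that did not pass the filter, such as AXIN2, stay open. That 2 h is too short, or that the dose left β-catenin unchanged, was not tested, and no biological explanation was tested here.

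For each comparison, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split gave 260 probe sets for BIO against vehicle (highest other 19, vehicle replicates 1 and 2 with BIO replicate 1), 3 for BMP4 against vehicle (highest other 0) and 102 for BMP4 against BIO (highest other 1), and in each 1 split, the real one, gave as many.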
